A study of Mus musculus with 2 samples.

How the data were processed

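The series holds 2 single-cell RNA libraries from whole mouse testis, 1 from Prm2 +/- and 1 from Prm2 -/- mice. Per the labels' protocols, tubules were isolated mechanically and digested with collagenase and then Accutase, with a wash to deplete Leydig cells. Then 15000 cells per library entered the 10x Genomics Chromium 3' v3.1 kit. The deposited files give UMI counts per gene and cell barcode, made with Cell Ranger 7.1.0 per the file headers. The submitters' processing notes name Cell Ranger, Seurat 4.1.0 and the mm10 genome build, and do not say what Seurat did to the deposited counts. The files hold whole numbers, 32285 Ensembl gene IDs with symbols and no barcode under 500 UMIs, so barcodes had been called as cells before deposit. Cell types were assigned here. No columns of other samples were present (0). Positions come from GENCODE M21 on mm10, in which 32158 of the IDs were found.

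Cells with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept, 15038 of 15210 in the heterozygous and 22503 of 22885 in the knockout library. Doublets were called with Scrublet in scanpy 1.11.5 in each library, with an expected rate of 0.8% per 1000 barcodes (12.0% and 18.0%) and its automatic threshold. It marked 462 cells (3.07%) and 3540 cells (15.7%), which were removed, leaving 14576 and 18963 cells. If both libraries were loaded alike, as the protocol gives, doublets may remain in the heterozygous library. The 2 libraries were clustered together without integration: log of counts per 10000, 2000 variable genes chosen within library, 30 principal components, 20 neighbours and Leiden resolution 1. The 5 protamine and transition protein genes, Xist, mitochondrial genes and Y genes were left out of the variable genes. This gave 24 clusters.

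Clusters were named from 14 marker sets fixed before the data were examined, as were the filters, clustering settings, size rule, gene lists, rule for naming genes and most of the other settings tried. The scoring rule for names was set after the data were seen. It took the set with the highest mean standardized level (at least 0.5 and 0.25 ahead of the next) with at least 3 markers above 10 CPM, and left unnamed any cluster whose 10 leading genes held more markers of another class, or with a low median UMI count and none of its own markers in front. Barcodes with over 1% hemoglobin UMIs (13 and 28) were counted as red blood cells. Classes merge clusters of the same name and are called "like" that cell type.

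UMIs were summed over the cells of a class in each library and scaled to CPM. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and all for counting error only. Where a library had 0 UMIs of a gene, a floor of 3 counts was used. Genes at 50 CPM or more in at least 1 library and with 100 or more UMIs over both were compared, and a 2-fold difference (log2 of 1) is a rule of size, not a test. Shares of cells with a Prm2 UMI were taken after thinning each cell to 2531 UMIs, the 20th percentile of spermatids in the shallower library. With 1 library per genotype no test, p-value or standard error was computed.

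The genes named are, in round- and elongating-spermatid-like cells, the 10 highest and 10 lowest log2 ratios under the size rule, leaving out clone-based and predicted names. In spermatogonia-, early-spermatocyte-, late-spermatocyte- and Sertoli-like cells they are the 3 highest and 3 lowest. The 5 protamine and transition protein genes are named in any class, and up to 4 members of each list with the largest absolute ratio in each spermatid class. Cell type markers are named to describe clusters. Some genes that meet these rules are not used here. The 17 lists were protamines and transition proteins, testis histone variants, histone eviction and acetylation, DNA break response and repair, apoptosis and p53 targets, oxidative stress defence, acrosome and sperm-egg fusion, flagellum and axoneme, manchette and head shaping, sperm glycolysis and energy, stored mRNA and translation control, spermatid transcription factors, heat shock and unfolded protein response, dissociation-induced early genes, multicopy sex-chromosome and Y genes, cytosolic ribosomal proteins, and mitochondrially encoded transcripts. The median log2 ratio of each list was placed among 10000 random lists of the same size drawn within 20 bins of mean expression.

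Other settings tried were at least 1000 UMIs per cell, at most 10% mitochondrial UMIs, all cells kept, each library clustered on its own, Leiden resolutions 0.5 and 2, genes scaled within each library, TMM factors from edgeR 4.0.16, each cell weighted equally, clusters weighted equally, cells thinned, minimums of 10 and 200 CPM, and other thinning depths. Scaling genes within each library was planned for class shares, and its use for gene values, alone and with clusters weighted equally, was added after seeing that elongating clusters split by library. The steps from sums to ratios were tested on simulated counts drawn from the real class totals with genes changed 3-fold. Apart from those genes both simulated libraries had the same profile and differed by counting error only. The results check the calculation and are not error rates for the real libraries. In late-spermatocyte-like cells 192 of 192 changed genes passed 2-fold and 0 of 3740 unchanged genes did (3932 genes). In round-spermatid-like cells these were 188 of 188 and 0 of 3510 (3698 genes), and in elongating-spermatid-like cells 192 of 192 and 0 of 2178 (2370 genes). Of 100 unchanged lists, 1, 6 and 6 fell outside the central 95%. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.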

Results

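Whole testes were dissociated to single cells and their RNA counted in 1 library from heterozygous (Prm2 +/-) and 1 from knockout (Prm2 -/-) mice. Prm2 encodes protamine 2, a small basic protein that replaces most histones on sperm DNA. The comparison asks how testis cells, and spermatids above all, differ between the genotypes. The heterozygous library held 71364845 UMIs (unique molecular identifiers, each a counted RNA molecule) in 15210 cell barcodes, with a median of 1882.5 UMIs and 1220 genes per barcode. The knockout library held 123588822 UMIs in 22885 barcodes, with medians of 3716 UMIs and 1805 genes. The protocol gives 15000 cells loaded for each. Both libraries hold more barcodes than that, and 18963 were kept in the knockout library after filtering and doublet removal. Either some barcodes are not separate cells or the loading figure is inexact, which was not tested. Shares of cells below are therefore shares of kept barcodes. With 1 library per genotype no test was possible, the differences have no replicate check, and every interval below is a 95% interval that covers counting error only.

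Both libraries held the full series of male germ cells, and the named germ cell classes took a larger share of the knockout library while Sertoli-like and Leydig-like cells took a smaller one. Round-spermatid-like cells made up 21.7% of the heterozygous library (3168 of 14576 kept cells, exact Clopper-Pearson interval 21.1 to 22.4%) and 27.2% of the knockout library (5154 of 18963, 26.5 to 27.8%). Elongating-spermatid-like cells made up 15.99% (15.4 to 16.6%) and 20.2% (19.6 to 20.8%), and late-spermatocyte-like cells, from pachytene to secondary, 17.3% (16.7 to 17.9%) and 21.6% (21.1 to 22.2%). The proportions between these stages were close, with 0.736 elongating per round spermatid in the heterozygous library (interval 0.697 to 0.776) and 0.744 in the knockout library (0.713 to 0.776). There were 1.26 round spermatids per late spermatocyte in both. Other settings moved these classes apart: knockout shares over heterozygous shares were 1.65 for late spermatocytes and 1.16 for round spermatids with at most 10% mitochondrial UMIs, and 1.62 for round and 1.23 for elongating spermatids at resolution 2.

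Spermatogonia-like cells made up 1.35% (1.17 to 1.55%) of the heterozygous library and 3.70% (3.43 to 3.98%) of the knockout library, and early-spermatocyte-like cells 3.77% (3.47 to 4.095%) and 5.63% (5.31 to 5.97%). The latter name is weak: heterozygous Sycp1 and Dmc1 stood at 420 and 18.0 CPM there, against 2658 and 255 CPM in unnamed cluster 14 and 658 and 62.8 CPM in spermatogonia-like cells, and in the knockout library the late spermatocyte markers (2653 CPM) exceeded the early ones (2105 CPM). Sertoli-like cells, the somatic support cells of the tubule, made up 8.66% (8.21 to 9.13%) and 4.79% (4.49 to 5.11%). In the knockout library they came from cluster 10 and from cluster 23, which held 181 of its cells and 18 of the heterozygous library's. Leydig-like cells, the steroid-producing cells that the protocol depleted by washing, made up 2.04% (1.81 to 2.28%) and 0.949% (0.816 to 1.10%). Interstitial-stromal-like cells made up 0.638% (0.515 to 0.781%) and 1.17% (1.022 to 1.33%), and macrophage-like cells 0.199% (0.133 to 0.286%) and 0.274% (0.205 to 0.359%). No cluster took the name of peritubular myoid, endothelial, lymphoid or epididymal cells, and such cells inside other clusters were not counted. The interstitial stromal cluster had Acta2 among its leading genes and scored 3.30 for peritubular myoid against 3.77 for stromal markers.

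Clusters with no name held 28.2% (27.5 to 29.0%) of the heterozygous and 14.3% (13.8 to 14.8%) of the knockout library, under naming thresholds set after the data were seen. Cluster 3 alone differed by more than that gap, with 20.3% of heterozygous and 0.353% of knockout cells and a median of 964 UMIs in the heterozygous library, while the other unnamed clusters, 11, 14, 16 and 20, each took a larger share of the knockout library. Both files ended at 500 UMIs per barcode, and 20.8% of heterozygous against 8.86% of knockout barcodes lay below 1000 UMIs, a depth gap that can set these shares. Doublet removal also differed, taking 3.07% of the heterozygous and 15.7% of the knockout cells. Among named cells alone the late spermatocyte, round and elongating spermatid shares were 24.1%, 30.3% and 22.3% in the heterozygous library and 25.3%, 31.7% and 23.6% in the knockout library.

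**Figure D1:**
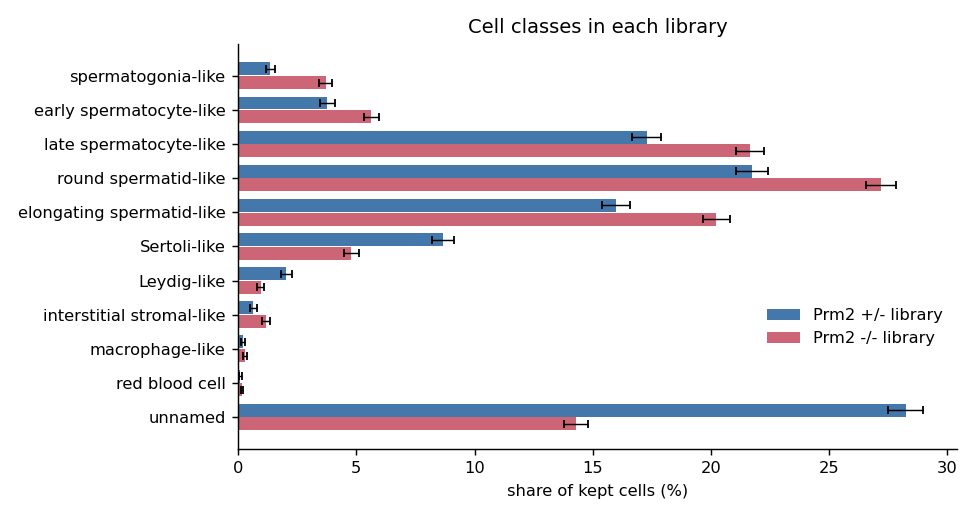
Share of kept cells in each class, in percent, for the Prm2 +/- library (14576 cells) and the Prm2 -/- library (18963 cells), with exact 95% Clopper-Pearson intervals for counting error as bars. The 3 largest named classes took 17.3%, 21.7% and 15.99% of the heterozygous and 21.6%, 27.2% and 20.2% of the knockout library, and unnamed clusters 28.2% and 14.3%.

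Prm2 UMIs were close to gone from both spermatid classes of the knockout library. The gene (ENSMUSG00000038015) lies on chromosome 16 from 10791380 to 10796134, on the minus strand (mm10). In elongating-spermatid-like cells it stood at 37315 CPM (UMIs of the gene scaled to a fixed total of the class) in the heterozygous library (600606 UMIs) and 13.8 in the knockout library (287 UMIs), 2706-fold lower (2411 to 3049). In round-spermatid-like cells it stood at 3445 CPM (65687 UMIs) and 6.13 CPM (212 UMIs), 562-fold lower (491 to 646). As CPM, the heterozygous round level was no higher than the 3589 CPM of spermatogonia-like and 10018 CPM of Sertoli-like cells. Much of it may therefore be free RNA, and the 562-fold may not describe mRNA made in round spermatids. The labels do not say which part of Prm2 was altered, and a 3' tag outside that part checks nothing, so these values describe transcripts that carry the counted end.

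With every spermatid thinned to 2531 UMIs, 98.95% of heterozygous spermatids (3772 of 3812 cells, 98.6 to 99.2%) and 2.38% of knockout spermatids (171 of 7191, 2.04 to 2.76%) held a Prm2 UMI. Thinning left out 1687 and 1797 shallower cells, and without it the shares were 100% and 5.18%. Free RNA, or doublets that remain, may have carried Prm2 UMIs into cells that should lack the gene in the heterozygous library. There 100% of thinned Sertoli-like cells (76 of 76) and 94.0% of late-spermatocyte-like cells held at least 1. The heterozygous share is therefore not above background. The level was above it in elongating-spermatid-like cells, at 37315 CPM against 10418 CPM in early-spermatocyte-like, 10018 CPM in Sertoli-like and 7144 CPM in Leydig-like cells. As CPM it was not above it in round-spermatid-like cells taken whole, at 3445 CPM, but these classes differ in depth. Per heterozygous cell, cluster 17 of the round class held more Prm2 (22037 UMIs in 339 cells) than Sertoli-like (16810 in 1262) or late-spermatocyte-like cells (40201 in 2519). In the knockout library 3.19% (2.64 to 3.81%) of thinned elongating-spermatid-like and 1.56% (1.18 to 2.02%) of thinned round-spermatid-like cells held a Prm2 UMI, against 0.372% (0.179 to 0.684%) of late-spermatocyte-like and 0.794% (0.0963 to 2.84%) of Sertoli-like cells. Median depths before thinning were 5988 and 4428 UMIs in elongating-spermatid-like cells of the heterozygous and knockout libraries, 2347 and 5565 in round-spermatid-like, 6587 and 5217 in late-spermatocyte-like and 956.5 and 1448 in Sertoli-like cells.

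The other protamine and transition protein genes stayed within 2-fold in both spermatid classes taken whole. In elongating-spermatid-like cells Prm1, the other sperm protamine, stood at 85978 CPM in the heterozygous and 63160 CPM in the knockout library, a log2 ratio of -0.44 (-0.45 to -0.44). Transition proteins pack DNA between histones and protamines, and Tnp1 (31489 and 26310 CPM, -0.26) and Tnp2 (43747 and 39048 CPM, -0.16) were also lower, as was Prm3 (4892 and 4286 CPM, -0.19). These ratios depend on scaling: the median of all genes in this class was 0.27, and edgeR's TMM shifts every ratio by -0.52. Under TMM the median of these genes and Prm2 together went from -0.26 to -0.78. In round-spermatid-like cells Prm1 was lower by a log2 ratio of -0.59 (-0.60 to -0.58), Tnp1 by -0.20 and Tnp2 by -0.15, and Prm3 was higher by 0.10 (0.08 to 0.12). The small ratios of Prm3 in round, and of Tnp1 and Tnp2 in both spermatid classes, changed sign with how cells were clustered or weighted. Weighting cells or clusters equally also put the median of Prm1, Prm3, Tnp1 and Tnp2 in the round class lower. Differences were larger inside the clusters of the round class, where Prm1, Tnp1 and Tnp2 stood at -1.70, -1.33 and -1.56 within cluster 5, -1.35, -0.95 and -1.12 within cluster 12, -0.87, -0.74 and -0.68 within cluster 4 and -0.60, -0.37 and -0.29 within cluster 17. Cluster 17, where these mRNAs stood highest, held 339 of the 3168 heterozygous and 1420 of the 5154 knockout round-spermatid-like cells. Heterozygous Prm1 in these clusters (5278 to 13613 CPM) lay below its level in Sertoli-like cells, where the log2 ratio was -1.55 (-1.87 in early-spermatocyte-like and -0.94 in spermatogonia-like cells). Heterozygous Prm1 totalled 29063 UMIs in 910 cells of cluster 4, 31691 in 993 of cluster 5 and 28874 in 926 of cluster 12. Per cell this was close to the level in Sertoli-like cells (39398 UMIs in 1262 cells). The differences in clusters 4, 5 and 12 may therefore be those of free RNA, which may also enter the whole-class ratios. CPM compares cells of unlike depth here, with heterozygous medians of 956.5 UMIs in Sertoli-like cells and 11115 in cluster 17. Per cell, heterozygous cluster 17 held more Prm1 (51198 UMIs in 339 cells) than Sertoli-like cells (39398 UMIs in 1262 cells).

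Elongating-spermatid-like cells came mostly from clusters 9 and 7 in the heterozygous library (51.9% and 32.9% of the class) and from clusters 7 and 6 in the knockout library (59.6% and 37.5%), and a cluster mostly of 1 library, such as cluster 9 here or unnamed cluster 3, may be that library and not a stage. Within cluster 9 the log2 ratios were -0.11 for Prm1, -0.01 for Tnp1 and -0.04 for Tnp2, and within cluster 6 they were -0.19, -0.06 and 0.03. Within cluster 7 Tnp1 (1.08) and Tnp2 (1.09) were higher in the knockout library while Prm1 was lower (-0.30), and within the small cluster 22 (63 and 36 cells) they were lower (-1.34 and -0.95), as was Prm1 (-0.96). Outside the spermatids these mRNAs were lower in the knockout library too, with Prm1 at 23479 against 7994 CPM in Sertoli-like cells and at 4265 against 1913 CPM in late-spermatocyte-like cells. Prm1, Prm3 and Tnp2 lie beside Prm2 on chromosome 16, from 10796326 to 10805839, 10790505 to 10790914 and 10787936 to 10788660, and Tnp1 on chromosome 1 from 73015074 to 73015909.

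**Figure D2:**
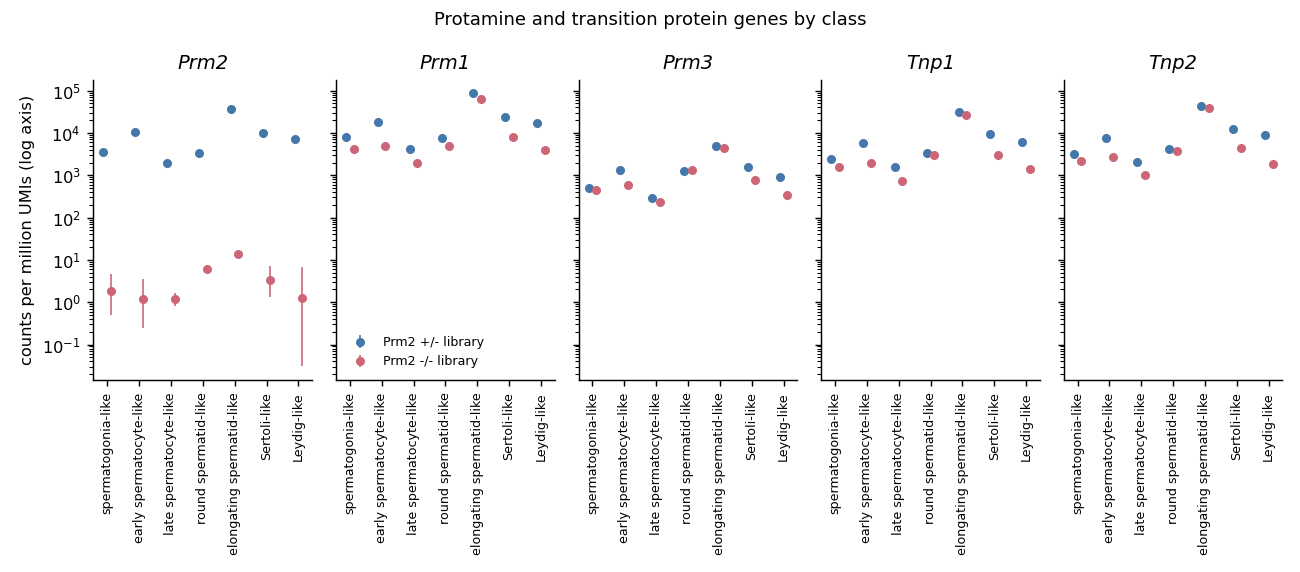
CPM (log axis) of Prm2, Prm1, Prm3, Tnp1 and Tnp2 in 7 cell classes of the Prm2 +/- and Prm2 -/- libraries, with exact Poisson intervals as bars. Prm2 was 2706-fold lower in knockout elongating-spermatid-like cells, while Prm1, Prm3, Tnp1 and Tnp2 stayed within 2-fold there, with Tnp1 and Tnp2 changing sign when clusters were weighted equally. TMM scaling shifts every log2 ratio of that class by -0.52.

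Round-spermatid-like cells of both libraries were close in most transcripts: of 3929 genes passing the size rule, 41 were at least 2-fold higher and 26 at least 2-fold lower in the knockout library. The 10 highest ratios under the naming rule were led by Fmn1, a formin that builds actin filaments (31.1 and 127.8 CPM, log2 2.04, interval 1.92 to 2.17). Next came Ppp4c, a protein phosphatase subunit (1.71), the small GTPase Arf5 (1.49) and Elavl1, an RNA-binding protein (81.6 and 220.3 CPM, 1.43). Chmp5, of the membrane-remodelling ESCRT machinery, stood at 1.41, the transcription factor Lhx2 at 1.40 and Tmem81, part of the sperm-egg fusion machinery, at 1.30. Kif16bos (1.25), the cyclin-dependent kinase partner Cks2 (1.23) and Fbxo39 (1.15) completed them. Chmp5, Kif16bos, Cks2 and Fbxo39 fell below 2-fold under some weightings of cells or clusters, to as little as 0.77, 0.98, 0.97 and 0.44.

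After Prm2, the lowest ratio under the naming rule, which leaves out predicted genes such as Gm10260 (-8.47), was that of Ntan1, an enzyme of the N-end rule of protein breakdown (61.5 and 4.77 CPM, log2 -3.69, interval -3.93 to -3.45). Rabgef1, an activator of endosomal Rab5, stood at -3.20, and Cdk8, a kinase of the Mediator complex, at -2.51. Lower by less were AY036118 (-1.79), the sodium pump regulator Fxyd2 (-1.75) and the mitochondrial ribosomal protein gene Mrps5 (-1.57). Cdk8 and AY036118 are uncertain because reads of ribosomal RNA repeats may have been counted to them. The histone gene Hist2h2aa1 (-2.17) shares sequence with near-identical genes, so its value is uncertain. H2-Ab1 of the class II histocompatibility region stood at -3.37, and is uncertain because read assignment and strain background were not tested. Most of the lower genes were also lower in late-spermatocyte-like cells, with Rabgef1 at -3.65 and H2-Ab1 at -3.22, whereas Ntan1 stood at -0.85 there.

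Of the 17 gene lists, 4 had a median outside the central 95% of 10000 random lists matched on size and expression in round-spermatid-like cells, as a description of these libraries. Cytosolic ribosomal protein mRNAs were lower, with 24 of 26 below 0, a median log2 ratio of -0.33 (percentile 0) and Rps3 (-0.66) and Rpl8 (-0.66) among the lowest. Flagellum and axoneme genes were lower, with 28 of 36 below 0, a median of -0.24 (percentile 0.03), and the axonemal dynein chains Dnah8 (-1.13) and Dnah17 (-0.95) and the sheath protein gene Fsip2 (-0.73) the furthest down, while Odf3 was higher (0.83). The same 2 lists had medians of -0.31 and -0.21 in late-spermatocyte-like cells, at percentiles 0 and 0.16. Apoptosis and p53 target genes had 4 members past the size rule, all above 0, with a median of 0.40 (percentile 97.8): Bcl2l11 (0.72), Mdm2 (0.61), Diablo (0.19) and Mcl1 (0.16). Early genes that tissue dissociation induces had 3 members, all above 0 with a median of 0.51 (percentile 97.9), namely Jund (1.05), Klf2 (0.51) and Klf4 (0.39). The ribosomal and flagellum lists stayed outside the random range under every setting run for lists (not resolutions 0.5 and 2 or 200 CPM), whereas the apoptosis list fell inside it under 6 settings and the dissociation list under 2.

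The other lists lay within the range of random lists in round-spermatid-like cells. Their medians were 0.14 for testis histone variants (10 genes, H3f3a 0.68, H3f3b 0.67), -0.07 for histone eviction and acetylation (11 genes, Dot1l -0.41, Phf7 -0.40) and 0.03 for DNA break response and repair (4 genes, Tdp1 0.49, Lig3 -0.36). They were 0.04 for oxidative stress defence (11 genes, Txn2 0.52, Prdx5 -0.51), 0.01 for acrosome and sperm-egg fusion (26 genes, Tmem81 1.30, Spaca5 0.74) and -0.02 for manchette and head shaping (26 genes, Ccin 0.78, Spata16 -0.62). Sperm glycolysis and energy stood at 0.00 (23 genes, Aldoart2 0.69, Bsg 0.60), stored mRNA and translation control at 0.08 (17 genes, Ybx2 0.92, Eif4e 0.76) and spermatid transcription factors at 0.20 (12 genes, Rfx2 0.58). Heat shock and unfolded protein response genes stood at -0.09 (12 genes, Hspa5 -0.58), multicopy sex-chromosome and Y genes at 0.30 (4 genes, Slxl1 0.60), mitochondrially encoded transcripts at 0.19 (10 genes, mt-Cytb 0.85) and the 5 protamine and transition protein genes at -0.20.

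Elongating-spermatid-like cells differed more: of 2567 genes, 196 were at least 2-fold higher and 24 at least 2-fold lower in the knockout library. The median of all genes was 0.27, and edgeR's TMM scaling shifts every ratio of this class by -0.52, after which 26 genes were higher and 103 lower. None of the genes named here from the highest and lowest ratios changes direction with that shift. Yjefn3 stood at 0.62 CPM (10 UMIs) in the heterozygous and 56.3 CPM (1172 UMIs) in the knockout library, a log2 ratio of 6.502 (5.62 to 7.57). Fmn1 was next (15.2 and 322.8 CPM, 4.41, interval 4.23 to 4.603), and Elavl1 (2.21), Arf5 (2.13) and Cks2 (2.05) were again among the 10 highest. Tmsb4x, which binds actin monomers, stood at 2.29, Tob1, a regulator of mRNA decay, at 2.27 and mt-Nd1, a mitochondrial complex I gene, at 1.92. Cst9 (3.09) and Aard (2.82) are leading genes of the Sertoli-like cluster, and the 12 Sertoli markers together stood at 78.0 CPM in the heterozygous and 331.6 CPM in the knockout elongating class, 4.25 times as high. Their sum was also higher in the other germ cell classes of the knockout library, 2.95-fold in round-spermatid-like (58.6 and 172.9 CPM), 2.99-fold in late-spermatocyte-like, 2.71-fold in spermatogonia-like and 2.48-fold in early-spermatocyte-like cells.

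Below Prm2, the lowest ratio in elongating-spermatid-like cells under the naming rule (Gm10260 stood at -9.57) was that of Bloc1s6, a subunit of an organelle biogenesis complex (59.8 and 1.92 CPM, log2 -4.96, interval -5.45 to -4.50). It stood at -4.31 in round-spermatid-like but -0.44 in late-spermatocyte-like cells. Cdk8 (-3.07), Cmss1 (-2.53), AY036118 (-2.05) and Lars2, the mitochondrial leucyl-tRNA synthetase (-1.64), were also lower. So were H2-Ab1 (-1.51) and Tcp10b (-1.45), both uncertain because read assignment was not tested, and H2-DMa (-1.38, but -0.91 with clusters weighted equally), of the class II region. Cdk8, Cmss1, AY036118 and Lars2 are uncertain too, because reads of ribosomal RNA repeats may have been counted to them. They were lower outside germ cells as well, at -2.83, -2.86, -2.94 and -1.05 in Sertoli-like cells. Markers of earlier germ cells were also higher in the knockout elongating class, late spermatocyte markers 1.98-fold and round spermatid markers 1.52-fold, and its own markers stood at 0.781 of the heterozygous level.

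**Figure D3:**
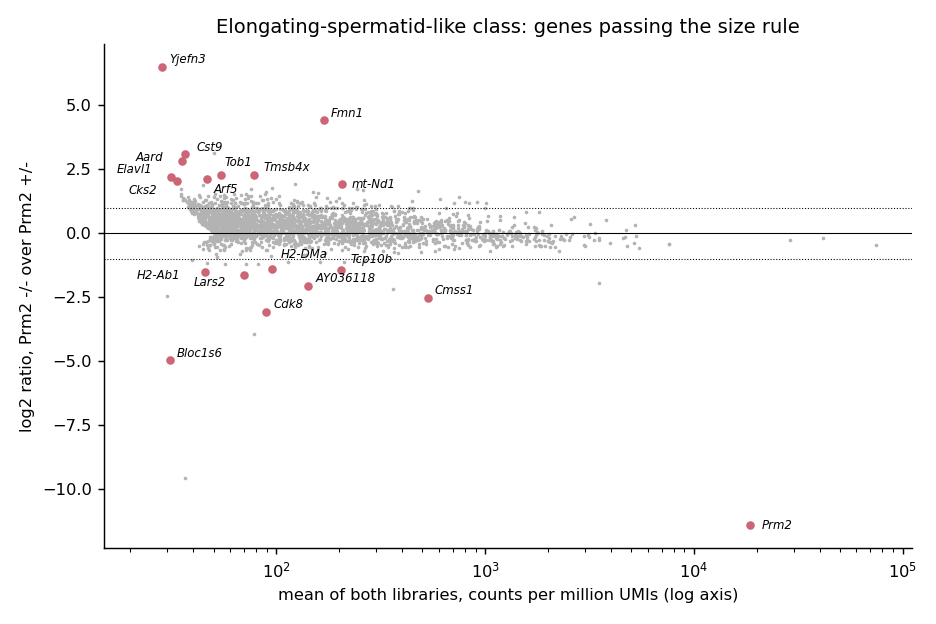
Log2 ratio of Prm2 -/- over Prm2 +/- against mean CPM (log axis) for 2567 genes in elongating-spermatid-like cells, with the named genes in red and the 2-fold limits dotted. Prm2 stood at -11.40 and Yjefn3 at 6.502, and 196 genes lay above the upper and 24 below the lower limit (26 and 103 after TMM scaling).

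Transcripts of the mitochondrial genome were the furthest above the rest in elongating-spermatid-like cells: 9 of 9 were at least 2-fold higher in the knockout library, with a median log2 ratio of 1.43 (percentile 100), 1.16 above the median of all genes and 0.91 under TMM. mt-Nd1 (1.92), mt-Cytb (1.73), mt-Nd4 (1.57) and mt-Nd3 (1.43) led them, and all mitochondrial UMIs together stood at 2192 and 5579 CPM. That sum was also 2.10-fold higher in early-spermatocyte-like, 1.52-fold in Leydig-like and 1.43-fold in Sertoli-like cells of the knockout library, but close in spermatogonia-like (1.09-fold), late-spermatocyte-like (1.03-fold) and round-spermatid-like cells (5745 and 5882 CPM). Stored mRNA and translation control genes were higher, with 11 of 11 above 0, a median of 0.83 (percentile 100) and 0.57 above all genes. Cpeb2, which acts on the mRNA tail (1.52), the germ cell mRNA-packaging proteins Ybx3 (1.20) and Ybx2 (1.17) and the tail-binding protein Pabpc1 (1.06) were the highest. Early and late spermatocyte markers were 1.94- and 1.98-fold higher in this class too, so a different mix of stages may contribute. This list stayed outside the random range in each setting run for lists, clusters weighted equally among them. Cytosolic ribosomal protein mRNAs were lower, with 16 of 23 below 0, a median of -0.20 (percentile 0) and -0.47 relative to all genes: Rpl8 stood at -0.62, while Rps2 (1.08) and Rpl5 (0.75) were higher.

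The remaining lists lay within the range of random lists in elongating-spermatid-like cells. Spermatid transcription factors stood 0.38 above all genes (10 of 10 above 0, Tbpl1 1.23, Rfx2 1.03, percentile 97.1), testis histone variants at -0.30 relative to them (9 genes, H3f3a 0.97) and the 5 protamine and transition protein genes at -0.53. Relative to all genes, histone eviction and acetylation stood at 0.24 (7 genes, Brdt 1.21, Cdyl 0.74), heat shock and unfolded protein response at 0.25 (12 genes, Hsp90b1 1.12, Pdia3 0.99), acrosome and sperm-egg fusion at 0.06 (13 genes, Fam170b 1.01, Zpbp 0.89) and flagellum and axoneme at 0.04 (23 genes, Odf3 1.29, Akap3 1.03), and the medians of these 4 lists are above 0 as CPM and below 0 under TMM. The same flip held for manchette and head shaping at 0.02 (21 genes, Ccin 1.00), sperm glycolysis and energy at -0.14 (19 genes, Slc16a7 1.19, Bsg 1.10), oxidative stress defence at -0.19 (11 genes, Sod2 1.13, Gstm5 -0.56) and multicopy sex-chromosome and Y genes at 0.06 (3 genes, Slxl1 1.01). The DNA break response (Polb 0.25), apoptosis (Bcl2l11 0.87, Mcl1 0.00) and dissociation (Klf4 1.14, Jund 0.85) lists had 1, 2 and 2 genes past the size rule, too few for a percentile, and Polb and Mcl1 lie below 0 under TMM.

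**Figure D4:**
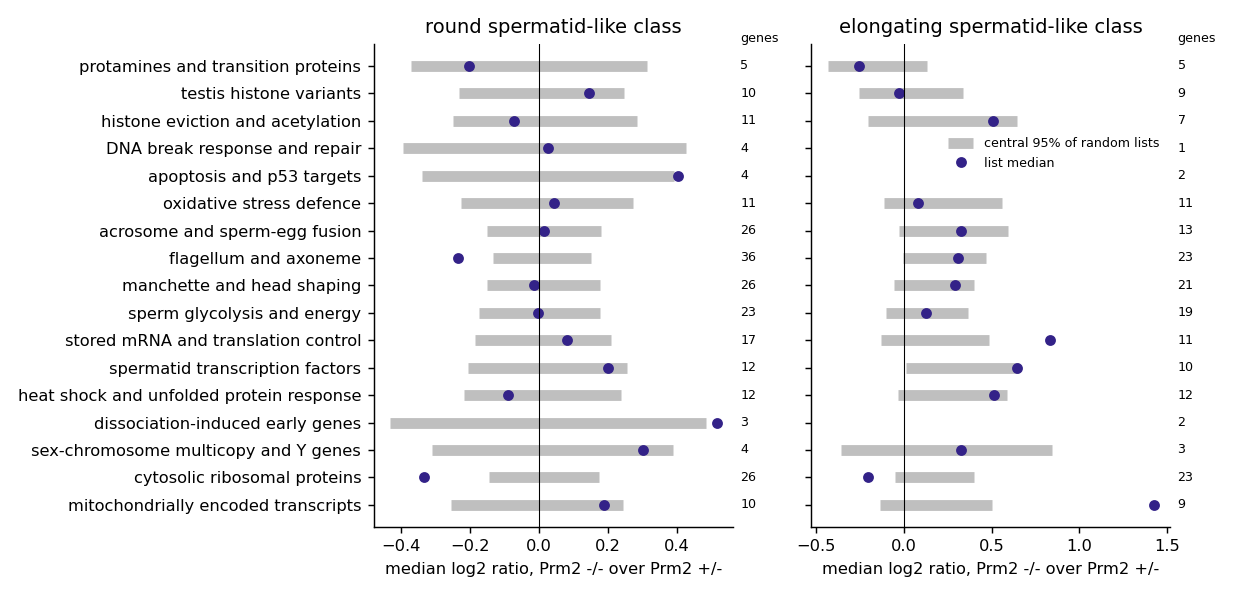
Median log2 ratio of Prm2 -/- over Prm2 +/- for each gene list (points) in round- and elongating-spermatid-like cells, with the central 95% of 10000 matched random lists as grey bars and the number of genes at the right. Ribosomal protein mRNAs lay below the range in both classes (-0.33 and -0.20) and mitochondrial transcripts above it in elongating cells (1.43), where 8 lists with medians above 0 lie below 0 under TMM scaling.

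Late-spermatocyte-like cells, which come before Prm2 is normally transcribed, give a rough measure of how far the libraries lie apart: of 4155 genes, 29 were at least 2-fold higher and 23 at least 2-fold lower in the knockout library. With the minimum kept at 50 CPM, other settings gave up to 140 such genes, 99 higher and 41 lower with genes scaled within each library and 39 higher and 72 lower with libraries clustered alone. A minimum of 10 CPM gave more. Alyref, an mRNA export factor (36.5 and 125.9 CPM, log2 1.79), Tmsb4x (1.56) and the actin-binding Pfn1 (1.496) were highest, and Prm2, Rabgef1 and H2-Ab1 lowest, under the naming rule (Gm10260 stood at -9.07). In these cells the testis histone variant list had a median of 0.40 (percentile 99.95), with 6 members above and 5 below 0. The protamine and transition protein list stood at -1.07 (percentile 0), with Prm1 at -1.16 and Tnp1 at -1.07. These ratios may be those of free RNA. Heterozygous Tnp1 totalled 31048 UMIs in 2519 late-spermatocyte-like cells, per cell close to Sertoli-like (15480 in 1262) and spermatogonia-like cells (2416 in 197). In spermatogonia-like cells 154 genes were higher and 23 lower of 5109, with the Sertoli gene Cst9 (2.63), Tmsb4x (2.52) and the glycerol kinase Gk2 (2.36) highest and, after Prm2, the histone genes Hist1h2ap (-2.83) and Hist1h4d (-2.22) lowest, both from multicopy families and so uncertain.

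In early-spermatocyte-like cells 292 genes were higher and 605 lower of 4882 (402 and 530 under TMM). Cst9 (2.81), Aard (2.17) and Tmem30c (2.00) were highest, and Ttn (-3.77, but -0.90 with all cells kept) and Cntn5 (-3.71, but -1.40 with all cells kept) followed Prm2 at the low end. In Sertoli-like cells 889 were higher and 187 lower of 4638, and with a TMM shift of -0.24 the split was 633 and 435. Phc3, a Polycomb component (3.20), Nkain2 (3.18) and the chloride channel Ano1 (3.13) were highest and, after Prm2, Hist2h2aa1 (-3.31) and AY036118 (-2.94) lowest. The higher values shifted with how the clusters of this class, of which cluster 23 was nearly all knockout cells, were weighted: over the settings run for gene values Phc3 ranged from 1.956 to 3.79, Nkain2 from -0.11 to 3.31 and Ano1 from 0.93 to 3.93. In Leydig-like cells 151 were higher and 310 lower of 3178 (93 and 362 under TMM, a shift of -0.11). Spermatid RNA, perhaps free RNA, differed in these classes: elongating spermatid markers stood at 17398 and 9722 CPM in Sertoli-like and at 13688 and 6419 CPM in early-spermatocyte-like cells.

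Genes near Prm2 on chromosome 16 were compared in round-spermatid-like cells. Of 49 tested genes within 10 Mb of it, Prm2 left out, 3 differed at least 2-fold, 6.12% (exact interval 1.28 to 16.9%), against 63 of 3879 elsewhere, 1.62% (1.25 to 2.07%). All 3 were lower in the knockout library and lay 2.56 to 3.04 Mb from Prm2. They were Ntan1 (13818845 to 13835451, log2 -3.69), Gm15738 (13354374 to 13468755, -3.14) and Pdxdc1 (13833148 to 13903131, -1.16). Gm15738 and Pdxdc1 fall outside the naming rule and were chosen after their values were seen, and Ntan1 and Pdxdc1 overlap, so their counts rest on reads being assigned by strand.

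**Figure D5:**
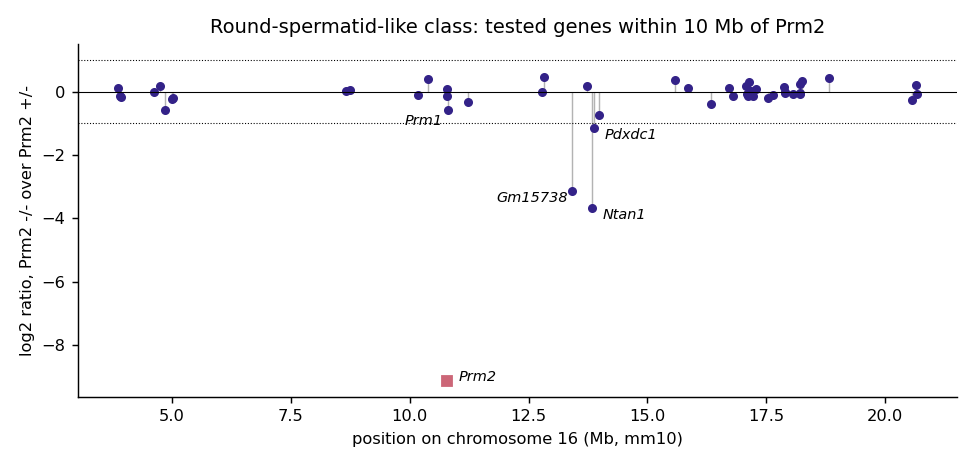
Log2 ratio of Prm2 -/- over Prm2 +/- in round-spermatid-like cells for the 49 tested genes within 10 Mb of Prm2 (points) and Prm2 itself (square), against position on chromosome 16 in Mb (mm10), with the 2-fold limits dotted. Ntan1 (-3.69), Gm15738 (-3.14) and Pdxdc1 (-1.16) lay below the lower limit.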

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

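The shares of unnamed clusters given here rest on naming thresholds chosen after the data were seen. They are listed because these cells enter no comparison between classes, and each took a larger share of the knockout than of the heterozygous library.

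Cluster 11 held 8.19% of knockout and 5.17% of heterozygous cells, with no marker set ahead of the others. Cluster 14 held 4.13% and 2.27%, scored highest for early spermatocyte markers and was led by Sdk1, Prss50, Stra8 and Dazl, among them a marker of spermatogonia. Cluster 16 held 1.15% and 0.295%, with elongating spermatid markers ahead of Sertoli markers by too little for a name, and Cst9, Defb36 and Cst12 leading. Its median doublet scores were 0.171 in the knockout and 0.277 in the heterozygous library. Cluster 20 held 0.464% and 0.199%, and was led by the antigen-presentation genes Cd74, H2-Eb1 and H2-Aa.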

How the results depend on the processing

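No paired analysis was possible because the libraries share only the number 1 and each genotype has 1 library. The cause of the shifts below was not tested, except that the CPM minimum sets how many genes are compared. Scaling genes within each library, alone or with clusters weighted equally, was chosen after seeing the data for gene values and lists.

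Ratios of knockout to heterozygous class shares kept their side of 1 under every setting that gave a value, and 34 of these values lay within counting error while 32 did not. With at least 1000 UMIs they were 2.24 (spermatogonia, against 2.74), 1.43 (late spermatocyte, 1.25), 1.12 (round, 1.25), 1.13 (elongating, 1.26), 0.814 (Sertoli, 0.554), 1.23 (stromal, 1.83) and 0.565 (unnamed, 0.506). With at most 10% mitochondrial UMIs they were 2.29, 1.65, 1.16, 1.34 and 0.492 for the first 5 of these, and 0.440 unnamed. With all cells kept they were 2.04 (early spermatocyte, 1.49), 1.11 (late), 1.17 (elongating), 0.618 (Sertoli), 0.702 (Leydig, 0.466) and 0.458 (unnamed). With each library clustered on its own they were 1.59 (late), 1.39 (round) and 1.36 (elongating). With genes scaled within each library they were 1.16 (late) and 0.644 (unnamed). At resolution 0.5 they were 1.33 (round), 0.657 (Sertoli) and 0.592 (unnamed), and at 2 they were 2.26 (spermatogonia), 1.30 (early), 1.54 (late), 1.62 (round) and 0.611 (unnamed). No such class formed, so no value was had, for spermatogonia at resolution 0.5, early spermatocytes with 10% mitochondrial UMIs or with libraries clustered alone, and stromal cells with libraries clustered alone.

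Resolutions 0.5 and 2 were run for class shares alone, and 200 CPM for gene counts alone. Prm2 was far lower under all settings run for gene values. In the round class it stood at -9.38 (10% mitochondrial), -10.11 (cells weighted equally) and -9.47 (clusters equal, genes scaled within library), against -9.13. In the elongating class it stood at -11.92 (TMM), -11.60 (cells equal), -11.63 (thinned) and -11.59 (clusters equal, scaled within library), against -11.40. The share of spermatids with a Prm2 UMI was 100% and 5.18% without thinning and 99.9% and 3.83% at 4956 UMIs. The median of Prm1, Prm3, Tnp1 and Tnp2, chosen over their mean after values were seen, in the round class (-0.18) turned to 0.0354 with all cells kept, 0.15 with libraries clustered alone and 0.0262 thinned, and stood at -0.41 (10% mitochondrial), -0.86 (cells equal), -0.64 (clusters equal), -0.11 (scaled within library) and -0.63 (both). In the elongating class (-0.22) it turned to 0.0757 with clusters equal, and stood at -0.23 (1000 UMIs), -0.23 (10% mitochondrial), -0.25 (all cells), -0.29 (clustered alone), -0.74 (TMM), -0.17 (cells equal), -0.17 (thinned), -0.22 (scaled within library) and -0.14 (both). Reversed single genes were, in the round class, Prm3 at -0.18 (cells equal), -0.24 (clusters equal) and -0.25 (both), Tnp1 at 0.10 (clustered alone) and Tnp2 at 0.0877 (all cells), 0.21 (clustered alone) and 0.0635 (thinned), and in the elongating class Tnp1 at 0.18 and Tnp2 at 0.19 (clusters equal).

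Genes past 2-fold numbered 141 (clustered alone), 258 (10 CPM) and 12 (200 CPM) in the round class, against 67. In the elongating class they numbered 505 (clustered alone), 129 (TMM), 1082 (10 CPM) and 51 (200 CPM), against 220. Similar counts can hold other genes: with clusters equal 83 of 166 elongating and 41 of 57 round genes were shared with the first result, and with genes also scaled within library 100 of 218 and 39 of 55. In the late spermatocyte class they numbered 105 (10% mitochondrial), 111 (clustered alone), 103 (cells equal), 140 (scaled within library), 179 (10 CPM) and 18 (200 CPM), against 52. In the round class the apoptosis list fell inside the random range with 10% mitochondrial, clustered alone, cells equal, clusters equal, scaled within library and 10 CPM, and the dissociation list with clustered alone and scaled within library. Lists outside the range numbered 2 (scaled within library) and 7 (with clusters equal too) in the round class, against 4, and 5 (clustered alone), 5 (clusters equal, scaled within library) and 9 (10 CPM) in the elongating class, against 3. The 3 elongating lists were among them in each setting run for lists. Nkain2 in Sertoli-like cells (3.18) turned to -0.107 with clusters equal and -0.0749 with genes also scaled within library. Over all values tried for genes named by rank, and for protamine and transition protein genes in the spermatid classes, 570 stayed past 2-fold (for the latter, inside the counting interval), 69 did not and 11 changed sign, and of list percentiles 316 kept their side of the random range and 25 did not. Depth limits what was compared: genes under 50 CPM were left out, and Sertoli-like cells had medians of 956.5 and 1448 UMIs.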

Other observations

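All tests below were chosen after the results they bear on had been seen.

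Genes that differed the same way in late-spermatocyte-, round- and elongating-spermatid-like cells were few. Of 1735 genes compared in all 3 classes, 11 were at least 2-fold lower and 3 at least 2-fold higher in the knockout library. The higher ones were Tmsb4x, Cks2 and the defensin gene Defb19, a Sertoli marker here, with log2 ratios of 1.63 for Defb19 in elongating- and 1.09 in round-spermatid-like cells. Among the lower ones were Prm2, Cdk8, Lars2, Cmss1, Tcp10b, H2-Ab1, AY036118, Pdxdc1, Gm42418 and Gm10260. These were named because they met this rule, after their values were seen. Gm42418, which carries ribosomal RNA sequence, stood at 5557 and 1465 CPM in elongating-spermatid-like cells, and Gm10260, a predicted ribosomal protein gene with near-identical copies and so uncertain, at 73.1 and 0.0961 CPM. AY036118 (39847113 to 39848035 on chromosome 17) lies inside Gm42418 (39846958 to 39848788), so their counts may not be independent. By chromosome, with Prm2 left out, 7 of 141 genes on chromosome 16 and 9 of 193 on chromosome 17 differed at least 2-fold in round-spermatid-like cells. Chromosome 11, among the lowest, had 1 of 314, chromosome X had 2 of 57 and chromosome 14 had 5 of 174. Over all genes, Prm2 included, the count was 67 of 3929 (1.71%).

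Mitochondrial transcripts were higher in knockout elongating-spermatid-like cells. A different mix of stages stays open: with clusters weighted equally the median log2 ratio was 0.985, or 1.10 with genes scaled within each library, against 1.43 pooled, but Tnp1 and Tnp2 differed over 2-fold within cluster 7 (1.08 and 1.09), so clusters may still mix stages. Against it, mitochondrial UMIs were higher by log2 1.52 within cluster 6 and 0.80 within cluster 9, where Tnp1 and Tnp2 stood at -0.06 to 0.03, and with genes scaled within each library Tnp1 and Tnp2 stood at -0.26 to 0.46 in the 3 large clusters, though alike markers do not make stages alike. Free RNA from Sertoli cells, tested with the fixed markers, stays open: the mitochondrial excess was 4.00% of the Sertoli level in the elongating class, inside the 1.17 to 4.23% of 8 Sertoli markers there, but 0.163% in the round class, below their 0.444 to 1.95%, and 0.657% in the late spermatocyte class, inside their 0.543 to 1.92%. A genotype effect on mitochondria in late spermatids may also remain and cannot be told apart from free RNA with 1 library each.

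Besides Prm2, 10 genes were lower in all 3 large germ cell classes. An effect of the genotype inside spermatids, seen elsewhere as free RNA, is argued against for most of them: in spermatogonia-like cells the difference was a median 89.8% of that in elongating-spermatid-like cells, against 9.62% for Prm2. The genes ranged from 11.2% (Tcp10b) and 21.7% (H2-Ab1) to 310% (Gm10260), and the value for Tcp10b alone excludes nothing. They were picked for being lower in late-spermatocyte-like cells too, which favours a broad difference, though Prm2 met the same rule. Those that may carry ribosomal RNA, named below, may be a single signal, so the median is not over 10 independent genes. Variants carried along with the altered gene can by definition lie only on chromosome 16. The 80% of these genes (8 of 10) on other chromosomes are therefore outside that explanation, and effects of such variants on distant genes were not tested. It stays open for the genes on chromosome 16, of which only Pdxdc1 lies within 10 Mb. In that window 6.12% of genes and elsewhere 1.62% differed 2-fold, with overlapping intervals. Reads of ribosomal RNA repeats counted to AY036118, Cmss1, Cdk8 and Lars2 also stay open, as their ratios to Gm42418 ranged a median 1.73-fold over 7 heterozygous classes but 2.11-fold for AY036118, and in the knockout classes 4.15-fold for Cmss1, 2.91-fold for Cdk8, 1.84-fold for AY036118 and 1.40-fold for Lars2. Strain background and a genotype effect in all cells were not tested.

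Knockout barcodes held 799 Prm2 UMIs, at most 6 in any barcode. Reads carried over by swapped indexes would be alike in all classes, but elongating-spermatid-like cells held 8.78 times (6.17 to 12.9) the Prm2 UMIs per cell of late-spermatocyte-like cells, and 4 of the 799 lay in the 88 barcodes found in both libraries. Evenly spread free RNA is argued against by the share of thinned cells with a Prm2 UMI, 3.19% (2.64 to 3.81%) in the elongating against 0.372% (0.179 to 0.684%) in the late spermatocyte class. Misassigned Prm1 reads would keep one ratio to Prm1, but Prm2 per Prm1 UMI was 5.74 times (4.78 to 6.88) as high in the round as in the elongating class. A transcript of the altered locus may be the source and was not tested, with 32.2 Prm2 per 10000 Prm3 UMIs in the elongating, 45.7 in the round and 52.8 in the late spermatocyte class.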
